A study of Mus musculus with 2 samples.

How the data were processed

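The series holds 2 ATAC-seq libraries of 1 group, haematopoietic stem cells of adult C57BL/6J mice, labelled as biological replicates 1 and 2. Both libraries carry the same donor identifier, per the labels, so whether they came from separate animals is unknown. The labels give sex as not collected and name no markers used to sort the cells. Spread between the libraries may therefore be technical in part, and p-values measured differences between genes or sequence windows, not between animals.

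The deposited files are ENCODE peak lists on mm10, per the labels. The aligner and the peak caller are not given in the sources used here, nor is the handling of the transposase's insertion offset. Per the deposited notes, each replicate has a list of peaks ranked by the irreproducible discovery rate (IDR), an IDR thresholded list and a pseudoreplicated list, called on that library alone. The series has ranked lists, an IDR thresholded list, a conservative IDR thresholded list, a replicated list and a pseudoreplicated list made from both libraries. The signal of each peak was deposited by the authors with no stated control or scaling. The −log10 p of each peak was deposited by the authors and was used only to trace lists to their inputs, and the −log10 q beside it was not used here. The IDR score of each ranked peak, up to 1000, was deposited by the authors. Thresholded lists held the ranked peaks with a score of at least 540, apart from 212 of 53453 peaks missing from the conservative list, 302 of 69188 from the other list of both replicates, 168 of 54079 from replicate 1's and 219 of 33712 from replicate 2's. The notes name an undescribed parent file, whose role in these losses was not tested. In the ranked list behind the conservative list, 83.1% of 111809 peaks carried replicate 1's values as the first input and 72.6% replicate 2's as the second, so this list compares the libraries.

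The conservative IDR thresholded list was the main list. Overlapping peaks of a list were merged into regions, with the summit and signal of the peak of highest signal. Genes came from GENCODE mouse release M21 on GRCm38.p6, with 21853 protein-coding genes on 21 chromosomes, and all 31532 main summits fell on called bases of that sequence. Promoters were TSS ±1 kb over all protein-coding transcripts. Summits were assigned in the order promoter, untranslated region (5′ and 3′ together), coding exon, intron and intergenic, and 100000 random positions, less those on uncalled bases, gave the background.

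The 21 gene lists (318 entries, all matched to the annotation), 22 consensus sequences, 16 enhancer elements, tests and alternatives were fixed before the data were examined. Promoter peaks per list were tested with two-sided Fisher's exact tests against all other genes, and log2 odds ratios used a correction of 0.5 per cell. Distal regions within 50 kb were tested against 10000 random lists, drawn with replacement, by two-sided permutation. Motif matches on either strand in windows of 201 bp (summit ±100 bp) were compared with the same windows shuffled by a two-sided exact McNemar test, and 1 of 20306 distal windows could not be used. Enhancers were tested by one-sided permutation with 10000 sets of random genes, and replicate differences per list by a two-sided exact McNemar test. Benjamini-Hochberg adjustment was made within each family at 0.05. Shares have 95% Wilson intervals, which cover counting error only. Chance overlap came from 100 shuffles.

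The genes named were fixed by rule: per list, the 3 members of highest promoter signal and up to 3, in alphabetical order, with no promoter peak in any list of either replicate; the 10 genes with most distal regions; the 10 distal summits of highest signal; all 16 enhancer elements; the Hox clusters by member; and up to 10 list members with a promoter peak in the IDR list of 1 replicate and in no list of the other. The lists of a replicate searched for promoter peaks were its IDR thresholded and pseudoreplicated lists, and its ranked list was not searched. Genes said to have no peak in either replicate had no promoter peak in those lists, and regions in no list of a replicate are meant likewise. Genes with near-identical copies (Hba-a1, Hbb-bs, Serpina1a, Tpsab1) are named as uncertain. Other genes were named after their values were seen, and some genes that the rule names are not reported here.

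Alternatives were the other peak lists, each replicate's own list, peaks above the median signal, other promoter, distal, motif and enhancer windows, overlap of 50% of both regions, lists matched on promoter GC content (10 bins) or TSS density (5 bins), flanking windows centred 500 bp from summits, the 5′-most TSS only, and equal numbers of regions. Matches of regions to mitochondrial DNA (e-value 1e-05) and to other places in the genome (e-value 1e-10) were found with blastn at 90% identity over 50% of the length. After the granulocyte difference was seen, lists of 16 other neutrophil genes, 12 macrophage genes and 10 plasma cell genes were written before their values were computed. The split of each list's genes with a promoter peak in 1 replicate only was then set against that of other genes by a two-sided Fisher's exact test.

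The tests of gene lists at promoters, of distal regions near gene lists and of motifs were run on simulated data, and the enhancer, replicate and matched-gene tests were not. Of 10 planted gene lists, 10 were recovered among 20000 genes for promoters and 10 for distal regions, with 0 of 10 unchanged lists called in each. Of 11 planted motifs in 5000 windows, 11 were recovered, and 1 of 11 unplanted motifs was called, E-box, whose sequence overlaps a planted MEIS instance. The planted differences were larger than those of the lists and motifs that did not pass here, and the planted genes were independent, unlike those of a Hox cluster. Full recovery therefore says nothing about the power to find smaller differences. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and BLAST+ 2.17.0 were used. Signal tracks and alignments were not used here. Absence from the shorter list of replicate 2 was not read as closed chromatin.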

Results

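Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in haematopoietic stem cells of adult C57BL/6J mice aged 5 to 6 weeks. The series holds 1 group of 2 libraries, labelled as biological replicates 1 and 2, so the comparisons were between the replicates, and between gene groups or genomic regions within the peak lists. The labels give a starting quantity of 50000 cells for replicate 2 and none for replicate 1. Read depth is unknown because the files used here list peaks and not reads. The main list, the series' conservative IDR list from a ranked comparison of both replicates, held 53241 peaks that merged into 31532 regions with a median width of 598 bp, covering 20.6 Mb or 0.756% of the genome. Each replicate's own list is its IDR thresholded list, which held 34588 regions for replicate 1 and 22434 for replicate 2. Each peak's signal is the authors' value. It was used to rank or describe peaks within a list, to correlate the replicates, to match genes and to compare sets of distal regions.

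The accessible regions of replicate 2 were largely contained in those of replicate 1, whose list was longer. Regions at gene promoters were shared between the libraries much more often than regions away from them. Of replicate 2's 22434 regions, 87.5% (95% Wilson interval 87.1 to 87.9) overlapped a region of replicate 1 by at least 1 base, and of replicate 1's 34588 regions, 56.5% (55.9 to 57.0) overlapped one of replicate 2. Regions shuffled within their chromosomes gave means of 1.59% and 1.04%. Promoters made up 47.0% of replicate 1's regions shared with replicate 2 and 15.8% of its 15063 other regions (log2 odds ratio -2.24, Fisher's exact test, two-sided, p below the smallest number the calculation could hold). In replicate 2 the shares were 47.2% and 16.2% (log2 odds ratio -2.21, two-sided Fisher's exact p = 2.36e-232). With equal numbers of highest-signal regions the log2 odds ratios were -3.01 for replicate 1 and -1.19 for replicate 2. Promoter and other regions were not matched on width or signal, which can both affect sharing. Across the 19525 shared regions, which are not independent replicates, signal ranks correlated with a Spearman coefficient of 0.672, higher at promoters (0.724) than at distal regions (0.598). Of replicate 1's regions, 86.4% overlapped the more permissive pseudoreplicated list of replicate 2, and 4693 were in neither that list nor replicate 2's IDR thresholded list.

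Accessible regions lay at promoters far more often than random positions did, and promoter regions were wider and had higher signal. Of the 31532 region summits, 35.6% (35.1 to 36.1) lay within 1 kb of the transcription start site (TSS) of a protein-coding gene, against 2.49% of random positions. Introns held 28.9% of the summits and 35% of random positions, and intergenic sequence held 32.7% and 60.2%. Coding exons (1.49%) and untranslated regions (1.27%) held few summits. Promoter regions had a median width of 836 bp and a median signal of 9.37, against 508 bp and 7.96 outside promoters. The promoter share was 33.4% in replicate 1's list and 43.3% in replicate 2's shorter list. A promoter peak was present in 11432 of 21853 protein-coding genes (52.3%).

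Housekeeping, cell cycle and cytokine receptor genes had a promoter peak in a larger share of cases than other genes did, although only the housekeeping call held against lists matched on promoter GC content. All 20 housekeeping genes had a promoter peak, led by Rplp0, a ribosomal stalk protein (signal 14.1), Hprt, a purine salvage enzyme (12.8), and Sdha, a subunit of mitochondrial complex II (12.8). Of the cell cycle genes, 16 of 18 had one, with the highest signal at Ccna2, encoding cyclin A2 (15.4), Top2a, a DNA topoisomerase (13.3), and Ccnb1, encoding cyclin B1 (12.9). The 2 without a main promoter peak were Ccnd1 and Cdkn2a, of which Cdkn2a had one in each replicate's own list. Cytokine receptor genes had one in 14 of 16 cases, led by the interferon receptor gene Ifnar1 (13.8) and the interleukin-1 receptor genes Il1rap (11.9) and Il1r1 (11.9), while Csf2rb, with a peak in replicate 1's list only, and Lifr had none in the main list. These missing members and those named for counts of 5 or fewer were chosen after their values were seen. Two-sided Fisher's exact tests against all other genes, adjusted over the 21 lists, gave log2 odds ratios of 5.23 for housekeeping genes (adjusted p = 5.68e-05), 2.59 for cell cycle genes (adjusted p = 0.00825) and 2.40 for cytokine receptor genes (adjusted p = 0.0167). Against random lists matched on promoter GC content, of these 3 only the housekeeping call remained (permutation adjusted p = 0.0021), at a log2 odds ratio of 4.40. Cell cycle genes had a log2 odds ratio of 1.65 (permutation adjusted p = 0.151) and cytokine receptor genes 1.89 (0.0701) against such lists. With peaks of above-median signal only, no list was above other genes (two-sided Fisher's exact adjusted p = 0.0773 for housekeeping genes, log2 odds ratio 1.43).

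The transcription factors that maintain stem and progenitor cells had promoter peaks in 15 of 20 cases (75%, 53.1 to 88.8), a share that did not pass the test (log2 odds ratio 1.36, two-sided Fisher's exact adjusted p = 0.0684). The highest signal was at Spi1, encoding the myeloid and lymphoid regulator PU.1 (8.42), followed by Meis1, a partner of HOX proteins (7.45), and Lmo2, a bridging protein of the TAL1 complex (6.87). The 5 without a main promoter peak were Gata2, Fli1, Hoxb4, Prdm16 and Bmi1. Fli1 and Bmi1 had one in replicate 1's own list (6.32 and 7.10), Hoxb4 in replicate 2's (5.62), and Gata2 in the pseudoreplicated list of each replicate. Prdm16 had none in any list of either replicate, but it had one in the list called on pooled reads, in which all 20 factors had one. Stem cell surface and marker genes had promoter peaks in 11 of 20 cases (55%), close to the share of other genes (log2 odds ratio 0.14, two-sided Fisher's exact adjusted p = 0.827). Flt3, a cytokine receptor of multipotent progenitors, had the highest signal (11.4), then Ctnnal1, a marker of stem cells (10.8), and Kit, the stem cell factor receptor (8.39). Ly6a, which encodes the Sca-1 antigen, had no promoter peak in any list of either replicate and had one in the pooled list, where all 20 surface and marker genes had one. The stem cell factor call depended on the peak list: with the IDR thresholded list of both replicates, which is longer, its two-sided Fisher's exact adjusted p was 0.0252 at a log2 odds ratio of 1.92. In the replicated list and the pooled list both stem cell lists were above other genes (log2 odds ratios 4.42 and 4.34 for each, two-sided Fisher's exact adjusted p = 0.00255 and 0.00333). With above-median signal only, the direction for stem cell factors turned (log2 odds ratio -1.61, adjusted p = 0.0571 by the same exact test). The small log2 odds ratio of the surface and marker genes was negative in 5 of the alternatives, among them the IDR thresholded list (-0.13).

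In the main list, genes of mature blood lineages had a peak at a minority of promoters. The share was 5 of 22 for granulocyte and monocyte markers, 2 of 12 for mast cell, basophil and eosinophil markers, and 2 of 13 for natural killer cell markers. These 3 lists were below other genes in the two-sided Fisher's exact test (log2 odds ratios -1.81, -2.21 and -2.34, adjusted p = 0.0231, 0.0342 and 0.0233). Among granulocyte and monocyte genes the transcription factors Irf8 (signal 8.79) and Cebpa (7.54) led, followed by the lysozyme gene Lyz2 (5.72), Itgam (5.27) and Fcgr3 (4.23), while the neutrophil protease genes Elane and Prtn3 had no peak in any list of either replicate. This list was not below other genes in replicate 1's own list, in which 13 of 22 members had a promoter peak (log2 odds ratio 0.35, adjusted p = 0.741 by the same exact test), against 3 in replicate 2's. In the pooled list the counts were 19 of 22, 6 of 12 and 8 of 13, and none of the 3 lists was below other genes there or in the replicated list. The granulocyte log2 odds ratio was 1.46 in the pooled list and 0.64 in the IDR thresholded list, neither passing (two-sided Fisher's exact adjusted p = 0.109 and 0.511). The natural killer call was also lost in the IDR thresholded list (0.393) and with replicate 1's list alone (0.0724), and the mast cell call with above-median signal only (0.109) and with the 5′-most TSS only (0.0588 by the same exact test). With promoters of ±2500 bp the granulocyte call was lost (two-sided Fisher's exact adjusted p = 0.155). Against lists matched on promoter GC content the log2 odds ratios were -1.50, -1.18 and -1.44, and none of the 3 calls passed (permutation adjusted p = 0.0640, 0.330 and 0.207). The 2 open mast cell genes were Hdc, the histamine-forming enzyme (7.81), and Cpa3, a mast cell protease (7.79). In replicate 2 both had a promoter peak in the pseudoreplicated list and not in the IDR list, and Cma1, Fcer1a and Mcpt8 had no peak in either replicate. The 2 open natural killer genes were Klrd1 (10.6) and Cd244a (6.21), both encoding surface receptors, and Eomes, Gzma and Il2rb had none in either replicate. Mcpt8 and Eomes had one in the pooled list. The near-identical copy Tpsab1 had no promoter peak in any list, which is uncertain because reads cannot be assigned between copies.

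Erythroid markers had promoter peaks in 7 of 20 cases, megakaryocyte markers in 7 of 16, B cell markers in 5 of 18 and T cell markers in 6 of 20, and none of these 4 lists passed the two-sided Fisher's exact test (adjusted p = 0.207, 0.684, 0.0785 and 0.0926, log2 odds ratios -0.98, -0.47, -1.43 and -1.29). Open erythroid promoters were led by Hemgn (signal 11.1), Ank1, a membrane skeleton protein (10.5), and Epor, the erythropoietin receptor (9.83). Gata1, the master regulator of red cell development, Alas2, the haem synthesis enzyme, and Rhag had no promoter peak in the IDR thresholded or pseudoreplicated list of either replicate. The globin genes Hba-a1 and Hbb-bs had a promoter peak in the permissive list of replicate 1 and not in the main list, which is uncertain because each has near-identical copies. Megakaryocyte promoters were led by Gp1ba, a platelet adhesion receptor (9.16), F2rl2 (8.30) and Rab27b (7.81), while Clec1b, Gp1bb and Gp6, which also encode platelet receptor proteins, had none in either replicate. The B cell list held the promoter of highest signal of all 21 lists, that of the complement receptor gene Cr2 (21.5), followed by the lineage factor Pax5 (9.34), Cd72 (7.20), Blnk (6.65) and Ebf1 (6.18), whereas Blk and Cd22 had none in either replicate. Cd3d (13.2), the adaptor gene Lat (11.9) and the costimulatory receptor gene Cd28 (11.3) led the T cell list, and Cd247, Cd3e and Cd3g had none in either replicate. With replicate 1's list alone both lymphocyte lists were below other genes (log2 odds ratios -1.85 for B cells and -1.65 for T cells, two-sided Fisher's exact adjusted p = 0.0281 for each). The B cell list was also below other genes in the replicated list, the pooled list and with above-median signal only (log2 odds ratios -1.89, -1.64 and -1.88, two-sided Fisher's exact adjusted p = 0.0145, 0.0433 and 0.0431). In the pooled list the counts were 15 of 20 erythroid, 11 of 16 megakaryocyte, 7 of 18 B cell and 9 of 20 T cell genes. The direction turned in the replicated and pooled lists for erythroid (log2 odds ratios 0.55 and 0.48) and megakaryocyte markers (0.12 and 0.045), again without passing.

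In the main list, genes of tissues outside the blood had a peak at few promoters. Hepatocyte markers had a peak in 1 of 12 cases (Apob, an apolipoprotein gene, signal 8.49), striated muscle markers in 2 of 12 (Actn2, 13.1, and Ttn, 9.61, both sarcomere genes), neural markers in 3 of 14 (Snap25, 15.2, Gad2, 5.48, and Mbp, 4.43) and marrow stromal and bone markers in 3 of 14 (Spp1, 13.3, Col1a1, 7.56, and Pdgfrb, 5.79). Gad2 had a promoter peak in the pseudoreplicated list of each replicate and in neither replicate's IDR list. All 4 lists were below other genes in the two-sided Fisher's exact test (log2 odds ratios -3.07, -2.21, -1.85 and -1.85, adjusted p = 0.00997, 0.0342, 0.0473 and 0.0473). Members with no peak in either replicate included the liver genes Alb, Apoa1 and Cps1, the muscle genes Acta1, Ckm and Myh1, the neural genes Dcx, Gad1 and Gfap, and the stromal genes Adipoq, Alpl and Bglap, although Alpl had one in the pooled list. Serpina1a, which has near-identical copies, had none in any list and is uncertain. Endothelial markers were open in 3 of 12 cases (Sox17, 7.91, Cdh5, 7.38, and Nos3, 7.28) and did not pass the test (log2 odds ratio -1.58, two-sided Fisher's exact adjusted p = 0.100). Stab2 had none in either replicate. With replicate 1's list alone and with promoters of ±500 bp the endothelial list did pass (log2 odds ratios -2.23 and -2.13, two-sided Fisher's exact adjusted p = 0.0281 and 0.0301), and the stromal list passed with neither replicate's list alone (0.138 and 0.146 by the same exact test). In the pooled list the counts were 3 of 12 hepatocyte, 3 of 12 muscle, 5 of 14 neural, 10 of 14 stromal and 11 of 12 endothelial genes. The direction turned in the replicated and pooled lists for endothelial (log2 odds ratios 2.00 and 1.92, two-sided Fisher's exact adjusted p = 0.122 and 0.180) and stromal markers (0.28 and 0.20). The neural call was lost in the replicated list (-1.33, two-sided Fisher's exact adjusted p = 0.146) and the muscle call with above-median signal only (-1.80, adjusted p = 0.109 by the same exact test). The stromal call was also lost in the IDR thresholded list (two-sided Fisher's exact adjusted p = 0.414) and with above-median signal only (0.0591), and both the stromal and the neural call with the 5′-most TSS only (0.0715 for each). Against lists matched on promoter GC content the calls for hepatocyte and stromal markers were lost (log2 odds ratios -2.21 and -1.80, permutation adjusted p = 0.0729 and 0.0640), and those for muscle and neural markers remained (0.0178 and 0.0329). With promoters of ±2500 bp none of the 4 calls remained (two-sided Fisher's exact adjusted p = 0.0836 for hepatocyte and muscle, 0.239 for neural and 0.526 for stromal markers).

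The 4 Hox clusters, which encode factors that pattern the body axis and of which the A and B clusters hold regulators of blood stem cells, had promoter peaks in the main list at some Hoxa genes, at 1 Hoxb gene and at no Hoxc or Hoxd gene. Of the 11 Hoxa genes 5 had a promoter peak, among them Hoxa4 (signal 8.49), Hoxa10 (7.88), Hoxa7 (4.88) and Hoxa9 (4.81), while Hoxa2 and Hoxa6 had none in either replicate. In each replicate's own list 3 of the 11 had one. The peaks of Hoxa4, Hoxa9 and Hoxb1 were in neither replicate's own IDR list. Hoxb1 (6.21) was the only one of 10 Hoxb genes with a main promoter peak. Hoxb5 had one in replicate 1's own list (6.47) and Hoxb4 in replicate 2's (5.62), while Hoxb13, Hoxb2 and Hoxb3 had none in either replicate. None of the 9 Hoxc genes and none of the 9 Hoxd genes had a main promoter peak (0%, Wilson interval to 29.9%), and Hoxc10, Hoxc11, Hoxc12, Hoxd10, Hoxd11 and Hoxd12 had none in either replicate, although Hoxc10 and Hoxb13 had one in the pooled list. The Hoxb, Hoxc and Hoxd clusters were below other genes (log2 odds ratios -2.8, -4.38 and -4.38, two-sided Fisher's exact adjusted p = 0.0231, 0.00825 and 0.00825) and the Hoxa cluster was not (-0.37, adjusted p = 0.805). Members of a cluster are neighbours and not independent, and the difference between clusters was not itself tested. Counts in the pooled list were 8 of 11 Hoxa, 5 of 10 Hoxb, 3 of 9 Hoxc and 2 of 9 Hoxd genes. In the pooled list the Hoxb and Hoxc calls were lost (two-sided Fisher's exact adjusted p = 0.413 and 0.109), as was the Hoxb call in the replicated list (log2 odds ratio -1.47, adjusted p = 0.152 by the same exact test). The Hoxa log2 odds ratio was positive in the IDR thresholded and pooled lists (0.33 and 0.26).

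**Figure D1:**
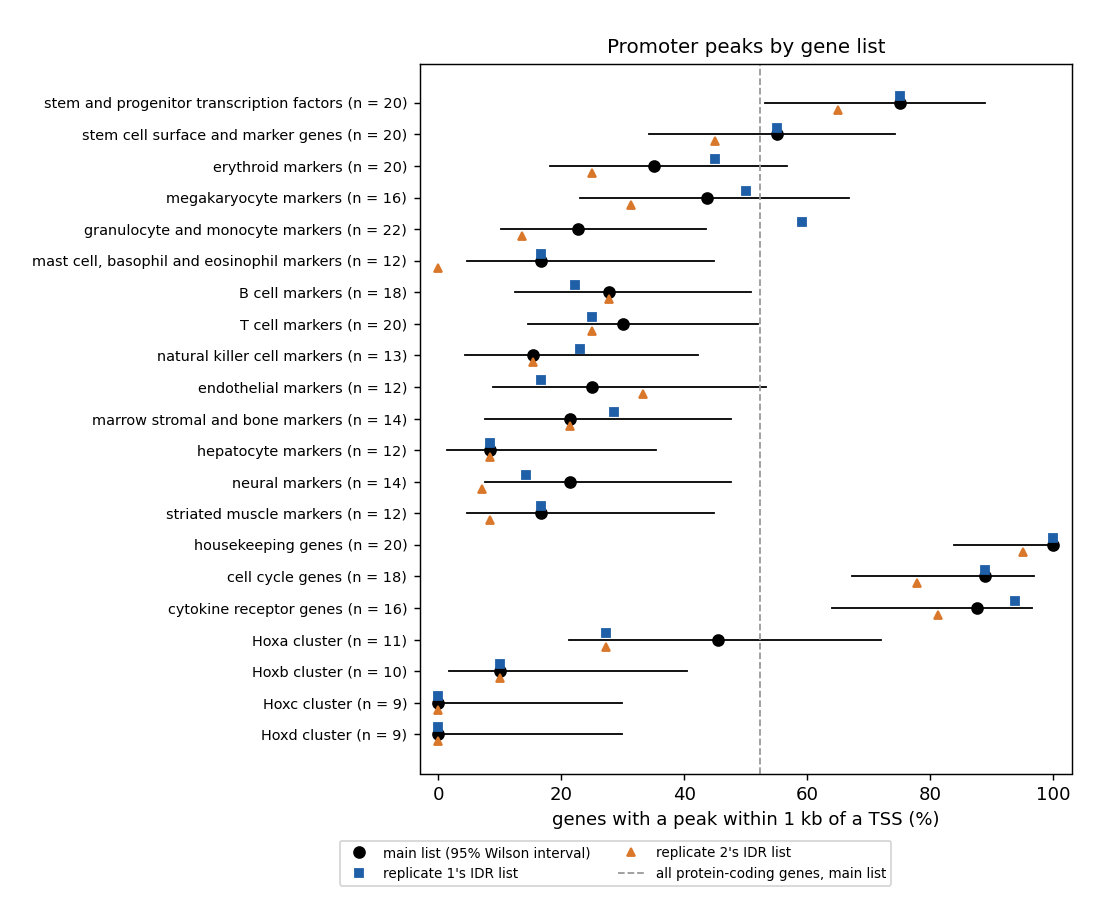
Share of each list's genes with a peak within 1 kb of a TSS (%), for the main list (black circles, 95% Wilson intervals), replicate 1's list (blue squares) and replicate 2's (orange triangles), with the 52.3% of all protein-coding genes as a dashed line. Housekeeping genes sit at 100% and the Hoxc and Hoxd clusters at 0%, and granulocyte and monocyte markers differ most between the replicates, at 59.1% and 13.6%.

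Distal accessible regions, those over 1 kb from every protein-coding TSS, were more numerous around stem cell transcription factor genes than around random genes. Counts were taken around every annotated TSS of a gene and not per kb, so long genes with several TSSs were searched over more sequence. The 20 stem cell factor genes had on average 3.80 ± 2.82 (SD over genes) distal regions within 50 kb, 2.62 times the mean of random gene lists, with 11 at Fli1, 7 each at Tal1 and Mecom, and 6 at Runx1, Lmo2 and Erg. Housekeeping genes had 1.97 times the mean of random lists, and granulocyte and monocyte genes had 2.68 ± 1.78 regions per gene. All 3 passed a two-sided permutation test against 10000 random lists (adjusted p = 0.0021, 0.0070 and 0.0084), with the unadjusted 0.0002 of the stem cell factors the smallest p these permutations can give. The Hoxa cluster had 0.182 ± 0.603 distal regions per gene and the Hoxc cluster 0, below random lists (permutation adjusted p = 0.00735 and 0.0021). Members of a Hox cluster are neighbours with overlapping windows, while the random lists hold unlinked genes, so the p-values of Hox clusters here overstate the evidence. Among all genes, 38.1% had no distal region. Both Hox calls were lost with replicate 1's list alone (permutation adjusted p = 0.683 and 0.491) and in each of the other 3 lists of both replicates. With above-median signal only, the granulocyte and housekeeping calls were lost (permutation adjusted p = 0.0580 and 0.137), as were the housekeeping call within 25 kb (0.148) and the granulocyte and Hoxa calls within 100 kb (0.0941 and 0.180). The other 16 lists did not pass the test, among them stem cell surface genes (2.30, permutation adjusted p = 0.0982) and cytokine receptor genes (2.56, 0.0826). Cytokine receptor genes passed in the replicated list (permutation adjusted p = 0.0361) and against lists matched on TSS density (0.0476), B cell genes with above-median signal only (0.0409), and the Hoxb cluster, above random lists, with replicate 2's list alone (0.0199) and in the replicated (0.0361) and pooled lists (0.0451).

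Over all 21853 genes the mean was 1.45 distal regions within 50 kb, and 38.1% of genes had none. The genes with most were Pde4d, a cyclic AMP phosphodiesterase (15), Trio, a signalling protein that acts on the cytoskeleton (14), Rere, a nuclear receptor coregulator (13), and Bcr, Cmip, Elmo1 and Pip4k2a (12 each), followed by the ETS factor genes Elf2 and Fli1 (11 each) and the chemokine receptor gene Cxcr5 (10). In replicate 2 alone these genes had 5 to 10. Regions were counted around every annotated TSS of a gene, and Pde4d spans 1504 kb with 12 of them.

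Most of the tested enhancers, named in the field by gene and distance, were accessible. Of 16 elements, 11 had an accessible region within 1 kb of their named distance from any annotated protein-coding TSS of the gene. Random genes given the same distances had a mean of 1.43 and a maximum of 7 (one-sided permutation p = 0.0001, the smallest these permutations can give). These random genes were not matched on their number of TSSs. The highest signal was at Gfi1 -35 kb (13.6, chromosome 5, 107759001 to 107759642, in an intron), followed by Cebpa +37 kb (9.68, chromosome 7, 35156331 to 35157054, intergenic), an enhancer of the granulocyte factor C/EBPα, and Runx1 +23 kb (8.58, chromosome 16, 92801472 to 92802163, intron). Tal1 had regions at +19 kb (8.12, chromosome 4, 115075323 to 115075899) and +40 kb (7.02, 115095597 to 115097017), both intergenic, and Spi1 at -14 kb (7.25, chromosome 2, 91082866 to 91083658), where the summit lies within 1 kb of an annotated TSS. Erg +85 kb had an intronic region (6.02, chromosome 16, 95439121 to 95439577). Gata2 -77 kb (6.98, chromosome 6, 88116346 to 88117594, intergenic), Gata2 +9.5 kb (5.69, 88202954 to 88203592, intron), Lmo2 -75 kb (6.58, chromosome 2, 103893724 to 103894219) and Myb -36 kb (6.48, chromosome 10, 21196611 to 21196976) had a region in replicate 1 and not in replicate 2. Coordinates are on GRCm38/mm10, counted from 1.

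No main region lay at Gata2 -2.8 kb, Tal1 -4 kb, Fli1 +12 kb, Gfi1b +16 kb or Myb -81 kb. Of these, Tal1 -4 kb had a region in replicate 1 and in the pooled list, and Fli1 +12 kb in the pooled list. Replicate 1's list covered 12 of the 16 elements and replicate 2's 7, and a region missing from the shorter list was not read as closed chromatin.

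**Figure D2:**
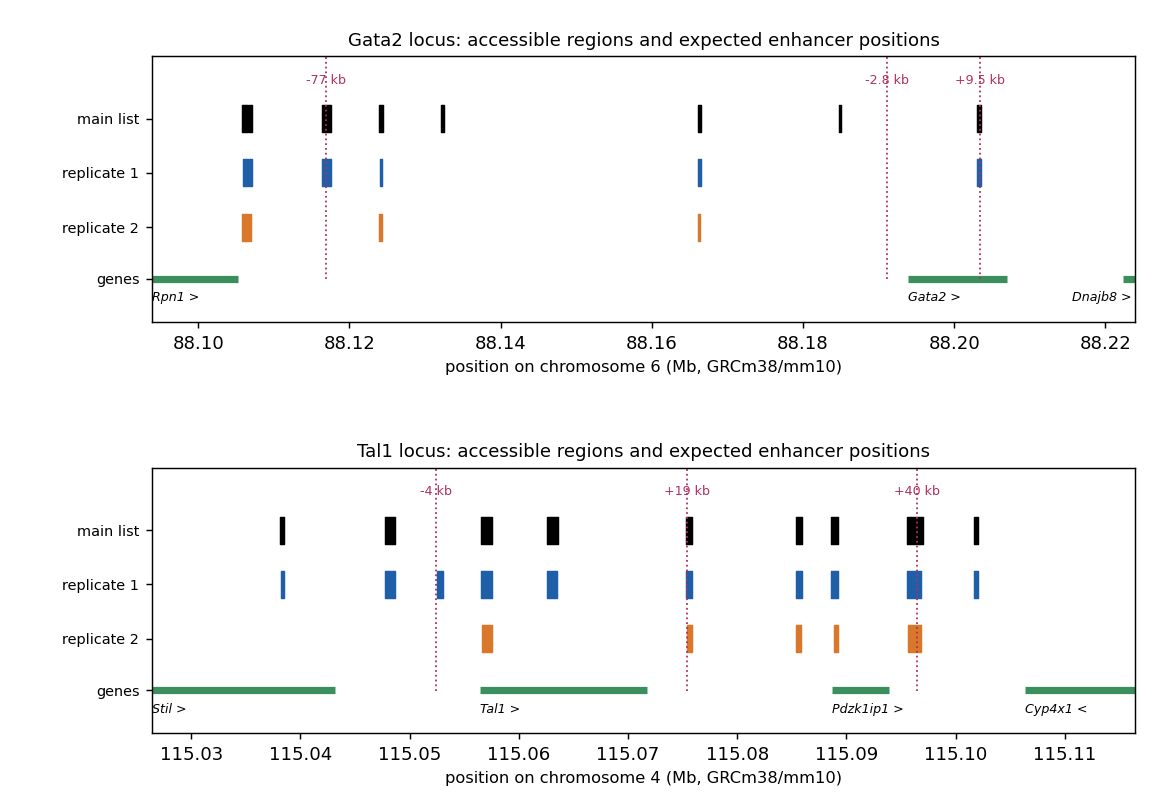
Accessible regions of the main list (black), replicate 1 (blue) and replicate 2 (orange) along chromosomes 6 and 4 (Mb, GRCm38/mm10) at Gata2 and Tal1, with genes in green (arrowheads give the strand) and the named enhancer distances as dotted lines. Main regions cover Gata2 -77 and +9.5 kb and Tal1 +19 and +40 kb, and none covers Gata2 -2.8 kb or Tal1 -4 kb.

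Distal regions carried the binding sequences of several blood transcription factors, though not of all those tested, more often than shuffled windows. Of 20305 distal summit windows, 24.8% (24.2 to 25.4) held an ETS match, against 4.98% of the same windows shuffled with dinucleotides kept, and the PU.1 sequence, a longer ETS variant, was in 5.60% against 0.404%. RUNX, the family of the stem cell factor RUNX1, was in 20.7% against 7.02%, and GATA, the family of GATA1 and GATA2, in 5.93% against 3.61%. The insulator protein CTCF had its sequence in 9.12% against 0.103%, and AP-1 in 8.08% against 3.93%. The C/EBP sequence of granulocyte and monocyte factors was below shuffled windows (9.15% against 11.0%, log2 ratio -0.26, two-sided exact McNemar adjusted p = 7.78e-10), but above them in replicate 1's list (12.6%, log2 ratio 0.12) and, in the main list, above flanking windows (log2 ratio 0.19). Within 50 bp of summits that difference did not pass (two-sided exact McNemar adjusted p = 0.148). The GATA difference had a log2 ratio of 0.71 (adjusted p = 9.59e-28 by the same exact test) and AP-1 1.04 (6.52e-71). Like C/EBP, MYB (4.37% against 5.54%) and MEIS (2.30% against 2.67%) were below shuffled windows (two-sided exact McNemar adjusted p = 1.33e-07 and 0.0255). Both had positive log2 ratios against flanking windows (0.28 and 0.38).

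At promoters KLF/SP was the most frequent sequence, and several of the sequences above were also over shuffled windows. KLF/SP, the GC-rich sequence of SP1 and Krüppel-like factors, was in 41.3% (40.4 to 42.2) of 11226 promoter windows against 13.7% after shuffling, and ETS in 19.9% against 4.57%. The cyclic AMP response element CRE was in 3.42% against 0.0891%, and NRF1, a regulator of mitochondrial genes, in 1.43% against 0.0445%. YY1 was in 1.17% of the windows and in none of the shuffled ones, which allows a share of up to 0.0267%. The PU.1 sequence was in 1.79% of promoter windows against 0.249%, CTCF in 1.43% against 0.232%, RUNX in 5.97% against 3.39% and AP-1 in 2.65% against 1.84% (two-sided exact McNemar adjusted p = 2.53e-33, 5.11e-25, 1.81e-20 and 6.84e-05). Against flanking windows the RUNX and AP-1 calls at promoters were lost (log2 ratios 0.046 and 0.21, adjusted p = 0.597 and 0.119 by the same exact test). Promoter and distal windows were not compared with each other by a test. GATA did not differ at promoters (1.54% against 1.36%, log2 ratio 0.18, two-sided exact McNemar adjusted p = 0.335) in the main list. It was above shuffled windows in the pooled list (adjusted p = 0.0169 by the same exact test) and within 50 bp of summits (0.0380), and below flanking windows (log2 ratio -0.93). Among sequences of factors of other tissues, HNF1, HNF4 and TEAD were not above shuffled windows in either class. MEF2 was above them in both (0.160% against 0.0356% at promoters, 0.414% against 0.148% at distal summits, two-sided exact McNemar adjusted p = 0.00597 and 6.93e-07). The consensus named neural E-box here was above them at distal summits (6.03% against 3.78%, adjusted p = 7.96e-26 by the same exact test) and not at promoters (2.45% against 2.29%, 0.502). A match does not tell which factor bound, and binding of this sequence by blood factors was not excluded, so it was not read as neural. Against flanking windows neither MEF2 difference passed (two-sided exact McNemar adjusted p = 0.510 at promoters, log2 ratio -0.41, and 0.573 at distal summits), and with replicate 2's list alone the one at promoters was lost (0.0520). The neural E-box at promoters was less frequent than in flanking windows (log2 ratio -0.42). Of the 44 tests, 28 were above and 7 below the shuffled windows. Windows and not animals were the units, and ETS, PU.1, PU.1-IRF and ISRE sequences partly overlap each other.

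**Figure D3:**
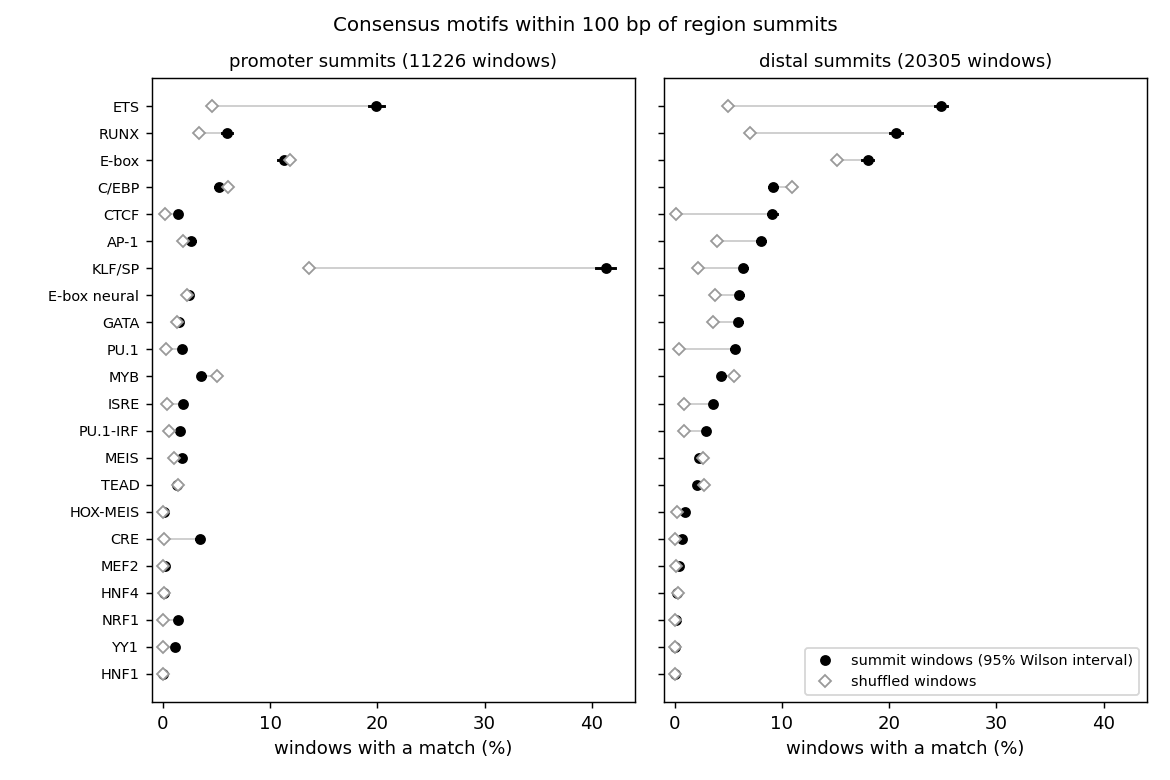
Share of windows within 100 bp of a summit that hold each consensus (%), for promoter (left) and distal (right) summits of the main list (black circles, 95% Wilson intervals) and for the same windows shuffled (open diamonds). KLF/SP leads at promoters, at 41.3%, and ETS (24.8%) and RUNX (20.7%) at distal summits.

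Of the 21 lists, granulocyte and monocyte genes had the largest share of members with a promoter peak in replicate 1's list only. Of the 22 genes, 10 had a promoter peak in replicate 1's list only, 0 in replicate 2's list only and 3 in both. The largest signals among genes absent from every list of replicate 2 were those of Ms4a3, a gene of granulocyte and monocyte progenitors (12.6), Fcnb, a ficolin (7.68), S100a8, a calcium-binding protein of neutrophils (7.02), Camp, an antimicrobial peptide (6.61), S100a9 (6.02) and Ngp, a neutrophil granule protein (3.73). The planned two-sided exact McNemar test gave p = 0.00195 (adjusted p = 0.0410 over 21 lists), but it takes no account of the greater length of replicate 1's list. Outside this list, Klf1, a red cell factor (10.2, and 8.42 in the main list), Hoxb5 (6.47) and Nkg7, a granule protein gene of cytotoxic lymphocytes (5.88), had a peak in replicate 1's list and in no list of replicate 2. Over all genes, 1739 (7.96%) had one in replicate 1's list only and 309 (1.41%) in replicate 2's only. Of the other genes with a promoter peak in 1 list only, 84.8% had it in replicate 1's, and the list's split of 10 and 0 did not differ from theirs in an added test (two-sided Fisher's exact p = 0.376, adjusted p = 1). No split of 10 genes leans further to replicate 1, so the test could not pass in that direction and decides nothing for this list. No list passed that test. Another added test set the list against all other genes: 45.5% (26.9 to 65.3) of its members and 7.92% of other genes were in replicate 1's list only (two-sided Fisher's exact adjusted p = 5.53e-05), and no other list passed. Both added tests were chosen after seeing the data.

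The granulocyte difference did not pass its test in every setting. With the permissive pseudoreplicated lists the counts were 10 and 1 (two-sided exact McNemar adjusted p = 0.246), and with equal numbers of highest-signal regions they were 1 and 1 (adjusted p = 1). With equal numbers 18 of the 22 genes had a peak in neither replicate, so the test could hardly show a difference there. In that last setting 751 of all genes had a promoter peak in replicate 1 only and 1777 in replicate 2 only. Stem cell factors (0 and 12, adjusted p = 0.0103 by the same exact test) and housekeeping genes (0 and 9, 0.0410) had promoter peaks in replicate 2 only there, and neither split differed from that of other genes (two-sided Fisher's exact adjusted p = 0.486 and 0.688). Both splits already lean as far to replicate 2 as they can, so the Fisher's tests could hardly show a further lean to it.

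**Figure D4:**
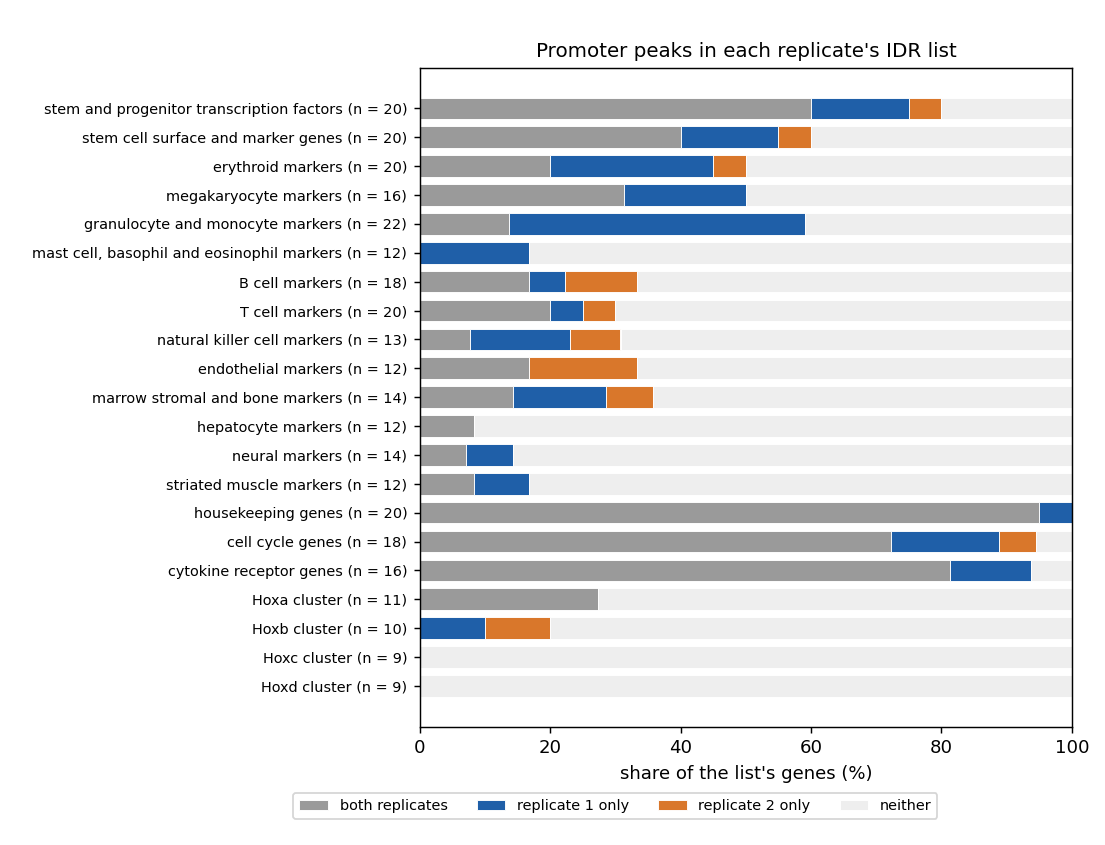
Share of each list's genes (%) with a promoter peak in both replicates' lists (grey), replicate 1's only (blue), replicate 2's only (orange) or neither (pale). Granulocyte and monocyte markers have 10 of 22 genes in replicate 1's list only and 0 in replicate 2's only.

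The 10 distal regions with the highest signal included 8 in intergenic sequence. The highest (signal 40.2) lay on chromosome 2 from 69355473 to 69355729, 13 kb from the TSS of Abcb11, a bile salt transporter gene. The next was on chromosome X (31.7, 143482940 to 143483174, nearest TSS of Pak3), then a region in an intron of Gnb1l on chromosome 16 (30.3, 18533127 to 18533395, nearest TSS of Rtl10). Intergenic regions followed on chromosome 6 (30.2, 9889878 to 9890221, Nxph1), chromosome 5 (29.7, 60042656 to 60043140, G6pd2), chromosome 8 (27.6, 20424176 to 20424965, Gm15319), chromosome 12 (27.0, 97061374 to 97061850, Galc), chromosome 8 again (25.8, 20122114 to 20122857, Gm31371) and chromosome 17 (25.3, 17004571 to 17005231, Zfp960). The last lay in an intron of Cldn34d on chromosome X (24.8, 76598531 to 76599189). All 10 had a signal in both replicates' lists. The regions on chromosomes 2, 6, 5 and 12 matched mitochondrial DNA over at least 50% of their length. Those on chromosomes 16, 8 and 17, and also those on 6, 5 and 12, had another match elsewhere in the genome. The signal of all these regions is uncertain.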

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

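The tests of replicate 1's own peaks and of the split between replicates, each against other genes, were chosen after the data were seen, and gave 1 list, as before, and 0; the other alternatives were planned. The number of known enhancers with a region, 11, was 7 to 14 under 8 alternatives, with a one-sided permutation p of 0.0001, the smallest possible, in each, and the promoter deficit of unshared regions kept its direction. The share of replicate 1's regions overlapped was 52.5% with overlap of 50% of both regions, 61.7% with pseudoreplicated lists and 53.9% with above-median signal, and that of replicate 2's 80.9%, 84.6% and 86.1%. The promoter share of summits was 29.7% in the IDR thresholded list, 23.1% in the replicated list, 21.1% in the pooled pseudoreplicated list, 37.3% above the median signal, 32.6% with promoters of ±500 bp, and 33.4% to 43.3% without either replicate. Lists above other genes at promoters numbered 5 in the replicated and the pooled list, 0 above the median signal and 1 against GC-matched lists, and lists below numbered 5 in the replicated list, the pooled list, with promoters of ±2500 bp and against GC-matched lists. Granulocyte and monocyte markers changed sign in the IDR thresholded list (0.64), the pooled list (1.46) and without replicate 2 (-2.26 to 0.35 without either replicate), stromal markers in the replicated (0.28) and pooled (0.20) lists, cell cycle genes above the median signal (-0.035), stem cell factors above the median signal (-1.61), endothelial (2.00 and 1.92), erythroid (0.55 and 0.48) and megakaryocyte markers (0.12 and 0.045) in the replicated and pooled lists, megakaryocyte markers against GC-matched lists (0.069), the Hoxa cluster in the IDR thresholded (0.33) and pooled (0.26) lists, and stem cell surface genes in the IDR thresholded list (-0.13), above the median signal (-0.29), with ±2500 bp (-0.014), against GC-matched lists (-0.26) and without replicate 1 (-0.056 to 0.12 without either replicate). For distal regions, 5 lists were above in the replicated list, 0 were below in the IDR thresholded, replicated and pooled lists, 0 to 2 without either replicate, and 1 within 100 kb. Distal log2 ratios changed sign for the Hoxd cluster in the IDR thresholded (0.12), replicated (0.70) and pooled (0.48) lists, above the median signal (0.013), within 25 kb (0.24) and 100 kb (0.28) and without either replicate (0.13 to 0.23), for muscle markers in the replicated (0.31) and pooled (0.21) lists, above the median signal (0.33), within 100 kb (0.35) and without replicate 1 (-0.11 to 0.36 without either replicate), for mast cell markers in the replicated (0.0087) and pooled (0.022) lists, above the median signal (0.018) and within 100 kb (0.12), and for erythroid markers within 25 kb (-0.0085). Tests of motifs below background numbered 3 within 50 bp. Distal C/EBP changed sign without replicate 2 (-0.36 to 0.12 without either replicate). Other motif log2 ratios that changed sign or went to 0 were those of E-box at promoters in the IDR thresholded (0.0048), replicated (0.060) and pooled (0.080) lists (-0.023 to 0.021 without either replicate), GATA (-0.21) and neural E-box (-0.16) at promoters above the median signal (-0.083 to 0.071 and -0.085 to 0.16 without either replicate), HNF4 at promoters in the pooled list (0; -0.096 to 0.11 without either replicate), distal YY1 above the median signal (0; 0 to 1.87 without either replicate), and distal HNF1 in the IDR thresholded (2.81), replicated (0.85) and pooled (0) lists, above the median signal (1.58), within 50 bp (0) and without either replicate (-0.74 to 0). Against flanking windows, log2 ratios changed sign at promoters for GATA (-0.93), E-box (0.34), HOX-MEIS (-2.23), MYB (0.066), ISRE (-0.40), PU.1-IRF (-0.26), MEF2 (-0.41), neural E-box (-0.42) and HNF1 (-1.58, from 0), and at distal summits for C/EBP (0.19), MEIS (0.38), HOX-MEIS (-0.058) and MYB (0.28). Lists differing between replicates numbered 0 with pseudoreplicated lists and 2 with equal numbers of regions. Of the remaining values, 143 kept direction and side of the threshold, 34 lost significance and 12 gained it for lists at promoters, 152, 13 and 6 did for distal regions, and 289, 21 and 10 for motifs. In all of these the cause was not tested. Read depth was unknown, so its limits were not measured.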

Other observations

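The tests of motifs by signal, of motifs by replicate, of the mitochondrial matches by part and of the length of replicate 1's list (all versions) were chosen only after the result was seen. Among distal regions, RUNX, ETS, PU.1 and ISRE sequences were more frequent where signal was higher. From the 10% of distal regions with the lowest signal (2031 regions) to the 10% with the highest (2030), the share with RUNX went from 15.7% to 26.7%, with ETS from 21.3% to 30% and with PU.1 from 4.38% to 7.59% (two-sided Fisher's exact adjusted p = 9.17e-17, 2.12e-09 and 0.000117). ISRE, bound by interferon regulatory factors, went from 2.66% to 4.19% (adjusted p = 0.0410 by the same exact test), and CTCF in the other direction, from 7.63% to 5.57% (0.0416), both below its 9.12% over all distal windows. Other sequences did not pass, among them GATA (6.11% and 5.62%), C/EBP (8.91% and 9.46%), MYB (4.58% and 4.19%), HOX-MEIS (0.837% and 1.03%) and PU.1-IRF (2.86% and 3.15%, adjusted p = 0.687 for each), MEIS (2.61% and 2.07%, 0.658) and AP-1 (7.83% and 9.06%, 0.499 by the same exact test).

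Of the 22 granulocyte and monocyte genes, 10 had a promoter peak in replicate 1's list only, 3 in both lists and 9 in neither. Among 3 lists written to follow this up, 9 of 16 other neutrophil genes had one in replicate 1's list only (56.3%, 33.2 to 76.9, against 7.92% of other genes, two-sided Fisher's exact p = 8.57e-07). Of these 9, Pglyrp1, Adam8, Padi4 and Mmp25 had one in a permissive list of replicate 2. Lcn2, Chil3, Cxcr2, Clec4d and Asprv1 had none in replicate 1's list. Of 10 plasma cell genes, 2 had one in replicate 1's list only (two-sided Fisher's exact p = 0.186). The 12 macrophage genes decide nothing, since none had a promoter peak in either list. The greater length of replicate 1's list is argued against for these other neutrophil genes. Of the 11 with a peak in replicate 1's list, 81.8% lacked one in replicate 2's, against 35.1% (9.09 to 63.6) of genes in the same bins of signal and promoter GC content (two-sided permutation p = 0.0044). With equal numbers of regions, 5 of the 16 had a peak in replicate 1 only and 1 in replicate 2 only, against 746 and 1776 other genes (two-sided Fisher's exact p = 0.0104). The split of 9 and 0 in the replicates' IDR lists did not differ from the 1730 and 309 of other genes (p = 0.371 by the same exact test). No split of 9 genes leans further to replicate 1, so that last test could not pass in that direction and decides nothing. For the granulocyte list itself the length explanation stays open. With equal numbers of regions the counts were 1 and 1 genes, but 18 of the 22 had a peak in neither replicate, so that setting decides nothing. The list's own tests ran on a list picked for the pattern and decide nothing either (52.6% of its genes without a peak in replicate 2's list had one in replicate 1's, and 76.9% of those with one in replicate 1's lacked one in replicate 2's). Distal regions of replicate 1 in no list of replicate 2 held the C/EBP sequence in 22.9% of 4318, against 9.56% of the 10352 shared ones (two-sided Fisher's exact adjusted p = 1.38e-93, log2 odds ratio 1.49). CTCF (8.94% against 6.23%, 7.81e-08) and MYB (5.26% against 4.31%, 0.0459 by the same exact test) were also more frequent there. PU.1, bound by a factor that granulocytes also use, was less so (4.08% against 6.25%, 6.20e-07), as were RUNX (15.5% against 22.8%, 3.43e-23) and ETS (22.7% against 27.8%, 1.34e-09 by the same exact test). Among other sequences, KLF/SP (2.76% against 7.70%, 3.10e-32) and E-box (12.2% against 19.2%, 1.41e-24 by the same exact test) were lower too. None of these shares, that of C/EBP included, was set against shuffled windows, and the sets of regions were not matched on base composition. Regions in no list of replicate 2 also had lower signal (median 7.89 against 10.4, promoters included). RUNX, ETS and PU.1 were rarer at low signal in the main list, so their deficits cannot be told apart from signal. Cells of the granulocyte lineage in replicate 1's sample, for which the 56.3% of other neutrophil genes was the test, or stem and progenitor cells closer to that lineage, are candidate explanations that the data cannot separate. The labels name no sort. Elane and Prtn3 had no promoter peak in any list of either replicate. Ly6g had none in replicate 1's IDR list but had one in its pseudoreplicated list, and none in any list of replicate 2. With 1 group, a difference in the stem and progenitor cells themselves was not tested.

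The 10 distal regions with the highest signal may hold misplaced reads, since 4 of them matched mitochondrial DNA over at least 50% of their length, against 0 of 1000 random distal regions, a count that decides nothing for the 10 as a whole. The 14 other distal regions with such a match had a median signal of 10.03, above the 7.96 of other distal regions (one-sided permutation p = 0.0060), which is consistent with mitochondrial reads placed on nuclear copies. That explanation is argued against for the other 6, whose highest matching share was 0%. Of those 6, 4 had another place in the genome that matched at least 50% of their length, against 23 of 1000 random distal regions (two-sided Fisher's exact p = 5.98e-06), so reads of repeated sequence placed on 1 copy are a candidate explanation for them. The mitochondrial-matching regions on chromosomes 6, 5 and 12 also had other places of this kind (6, 1 and 5), so for them these candidates cannot be told apart. The regions near Pak3 and in Cldn34d on chromosome X had neither kind of match and stay unexplained, and no biological explanation was tested.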
